A study of Leiocassis longirostris with 6 samples.

How the data were processed

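Small RNA libraries from catfish spleen were sequenced by the submitters, 3 after saline injection and 3 after Aeromonas hydrophila injection, and 2 deposited tables of the whole series were used. Groups and replicate numbers were taken from the sample titles and characteristics. The counts were deposited by the authors as whole numbers per mature miRNA and library, unnormalized, per the file headers. A block of log2 values per library was deposited beside them as the authors' normalized expression, per the file headers. Those log2 values were checked against the counts and equalled log2 of the count times 1 constant per library plus 1, to within a relative 3.6e-09, with constants between 0.259 and 0.538. They were used for that check alone. Back on the linear scale they summed to between 523868 and 752283 in 5 libraries and to 99840 in infected library 3. A further deposited table gave the precursor sequence of each miRNA in each library, and it reads null where none was listed. For zebrafish-named miRNAs 30, 21 and 15 precursors were not listed in control libraries 1, 2 and 3, and 11, 10 and 46 in infected libraries 1, 2 and 3. The genome build named in the submitters' processing notes is GRCz11, a zebrafish assembly. The mapping and prediction tools, the library kit and the strand setting were not given in the sources used here, and no genome was used, so no coordinates are reported. Mature sequences were not used here.

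Names are printed as the table gives them, with the prefix dre of zebrafish. Most predicted miRNAs have names without a family, and those antisense to a known precursor are described by it. Predictions that carry a family name stayed in the family lists, where 1 was tested (conserve-dre-miR-142-5p). Of 117 predicted rows, 49 had different precursors in different libraries under 1 name. Names that recur in the table (22 repeated rows) were kept as separate rows. Paralogs and arms of a family share sequence, and the authors' counting could have split or moved reads between them, so values of single paralogs are uncertain to that extent.

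All counts were analysed with edgeR 4.0.16 in R 4.3.3. Rows were filtered by filterByExpr by group, which left 261 (187 zebrafish-named and 74 predicted), scaled by TMM, and fitted with a robust quasi-likelihood model of intercept and group. P-values were adjusted by Benjamini-Hochberg over the 261, with a threshold of 0.05, and the count with at least a 2-fold change was taken beside it. CPM values use TMM-scaled library sizes. Standard errors of log2 fold changes were taken as the fold change over the square root of the F statistic. Wilson intervals at 95% cover counting error only, because PCR copies are not independent molecules. With library totals between 185497 and 2026263, the 3 counts that a counted 0 would allow correspond to 0.701 CPM over the controls and 0.655 CPM over the infected libraries, but no fold was taken from them because zeros here may be unlisted entries.

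Family lists were fixed before the data were examined, by family number with every arm and paralog, and tested with camera (limma 3.58.1) at a preset correlation of 0.01 when at least 3 members were tested. They were inflammation-responsive, fish interferon-inducible cluster, haematopoietic and myeloid, lymphocyte, erythroid, miR-17-92 and paralogs, let-7, miR-10/100/125, endothelial and smooth muscle, striated muscle, liver, pancreas, gut and kidney epithelium, miR-200 epithelial, neural, miR-29, miR-30, miR-15/16, hypoxia and miR-34. Some families stand in 2 lists, such as miR-155 and miR-223. The share of counts in the 10 most abundant miRNAs was compared by an exact two-sided permutation test. The miRNAs named were fixed by rule: all that passed when 30 or fewer did, with fewer than 10 passing the 5 smallest p-values in each direction as well, the 10 most abundant by mean share, and up to 4 members of each list by abundance, of which at most 2 were used. dre-miR-221-3p, dre-miR-203a-3p, dre-miR-722-3p, dre-miR-126a-3p, dre-miR-222b-3p, dre-miR-218a-3p, dre-miR-29b-3p, dre-miR-29b3-3p, conserve-dre-miR-142-5p and the miRNAs given with the quality-weighted test in the closing section were named after their values were seen.

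Each predicted row was classed by its precursor with the most counts, through the longest exact match of its reverse complement with known precursors. At least 20 bases counted as antisense. In each library, a row whose precursor there was antisense was paired with the opposite arm of the known miRNA. Ratios were taken where the known strand had at least 100 counts. The band of 1.2-fold replaced a somewhat wider one after the values had been seen, and the wider one held 69.4% of all 255 pairs. This step used Python 3.11.15 with pandas 2.3.3 and was chosen after the data were seen.

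Alternatives were DESeq2 1.42.0, limma voom with quality weights, other scalings and filters, the replicate number as a block, known miRNAs alone, the removal of the 3 most abundant miRNAs, a threshold of 0.1, an estimated correlation and fry for the lists, the top 1 and top 50 miRNAs for the share, and each library left out. Subsets of rows by listed precursor, sums per family, rows with identical counts collapsed, known miRNAs alone for the lists, and known miRNAs alone without infected library 2 or 3 were added after the data were seen. The test was checked on simulated data: 10 sets of 261 miRNAs with the means, library sizes and dispersions of these libraries and 40 of them changed gave median log2 fold changes of 1.07, 1.99, 3.01 and 6.09 for true 2-fold, 4-fold, 8-fold and 64-fold changes, and 0 calls in 10 sets without changes. At this dispersion the test recovered 0% of 8-fold changes, so its 0 calls say little about false calls. At 0.1 times the dispersion, 10 sets without changes gave 2 calls. With every member of the inflammation-responsive list raised 2-fold, camera called that list in 7 of 10 simulated sets and no other list. Simulated miRNAs were drawn independently of each other, so these sets cannot show how camera behaves when members are correlated.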

Results

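Small RNA reads from the spleen of fingerling Chinese longsnout catfish (Leiocassis longirostris, a farmed freshwater catfish) were counted per mature miRNA in 6 libraries. The spleen filters the blood of a fish and holds many of its immune and red blood cells. Control fish (3 libraries) had been injected in the body cavity with phosphate-buffered saline, and infected fish (3 libraries, with 12 h in their titles) with Aeromonas hydrophila, a bacterium that causes haemorrhagic septicaemia in fish. Each treatment had 20 fish and an injection of 100 µL. The labels do not say whether a library came from 1 fish or from several, so p-values measure only the spread between these samples, which may be technical. Control libraries 1, 2 and 3 held 1684375, 1546618 and 1351049 counts, and infected libraries 1, 2 and 3 held 1970028, 2026263 and 185497. The table had 365 rows under 343 distinct names, of which 248 rows carried zebrafish miRNA names and 117 were predictions by the authors. Infected library 3 was thus the shallowest, with 176 named zebrafish miRNAs above 0 against 208 to 229 in the other 5 libraries.

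The spleen miRNA pool was led by dre-miR-146a-5p, a feedback inhibitor of Toll-like receptor signalling, and dre-miR-21-5p, which many inflamed tissues express strongly. dre-miR-146a-5p stood at 212739 ± 102452 CPM (counts scaled to a common library size) in controls (SD, n = 3) and at 167815 ± 23063 in infected spleens (SD, n = 3). dre-miR-21-5p stood at 146662 ± 26717 CPM in controls and 138612 ± 28161 in infected spleens (SD, n = 3 each). The 10 most abundant miRNAs also held dre-miR-143-3p, known from smooth muscle, dre-miR-100-5p, dre-miR-30c-5p, dre-miR-30d-3p, dre-let-7e-5p and dre-miR-462-5p, which interferon induces in fish. The remaining pair were predicted miRNAs antisense to miR-146a and miR-21. Together these 10 took 65.2 ± 5.76% of the counts of the control libraries and 63.9 ± 4.98% of those of the infected libraries (SD, n = 3 each). The difference of -1.26 percentage points was within the spread between libraries (exact two-sided permutation p = 0.8, where 3 against 3 libraries cannot go below 0.1). It turned positive without control library 1 (2.03 points) and without infected library 2 (1.36 points). Both predicted rows among the 10 were at 0 in infected library 2, so the share of that library (58.7%) lacks them.

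Predicted miRNAs supplied between 22.4% (infected library 1, 95% Wilson interval 22.4 to 22.5%) and 25.9% (control library 1, 25.86 to 25.995%) of the counts in 5 libraries. In infected library 2 they supplied 1.37% (95% Wilson interval 1.35 to 1.38%). Each of the 117 predicted rows was classed by its precursor with the most counts, and its other precursors were not classed. In 90 rows the reverse complement of that precursor matched a known precursor exactly over at least 20 bases. The median match was 57.5 bases, and the longest among the other predicted rows, classed in the same way, was 12 bases. One example is the precursor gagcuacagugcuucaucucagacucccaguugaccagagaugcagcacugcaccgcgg, which contains the reverse complement of the 55-base miR-143 precursor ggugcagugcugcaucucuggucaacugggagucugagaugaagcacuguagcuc. The 90 antisense rows held between 22.3% and 25.8% of all counts in 5 libraries and 0.0290% in infected library 2 (95% Wilson interval 0.0267 to 0.0314%). Rows outside the 90 may hold antisense counts too. One of them, conserve-dre-miR-7550-5p, had 922, 881, 1038 and 55 counts in control libraries 2 and 3 and infected libraries 1 and 3. The antisense 5p row of miR-24 had 922, 881, 1036 and 55 there. Over the pairs of locus and library with at least 100 known-strand counts and a nonzero antisense count, those of infected library 2 left out, the antisense count was 0.453 times the known-strand count in the median. Of these pairs, 172 (77.8%) lay within 1.2-fold of the median of their library. A further 34 pairs had an antisense count of 0, and over all 255 pairs the share within 1.2-fold was 67.5%. The antisense row of miR-146a had 208436, 109947 and 93443 counts in the controls, 155753 in infected library 1, 0 in infected library 2 and 15368 in infected library 3.

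**Figure D1:**
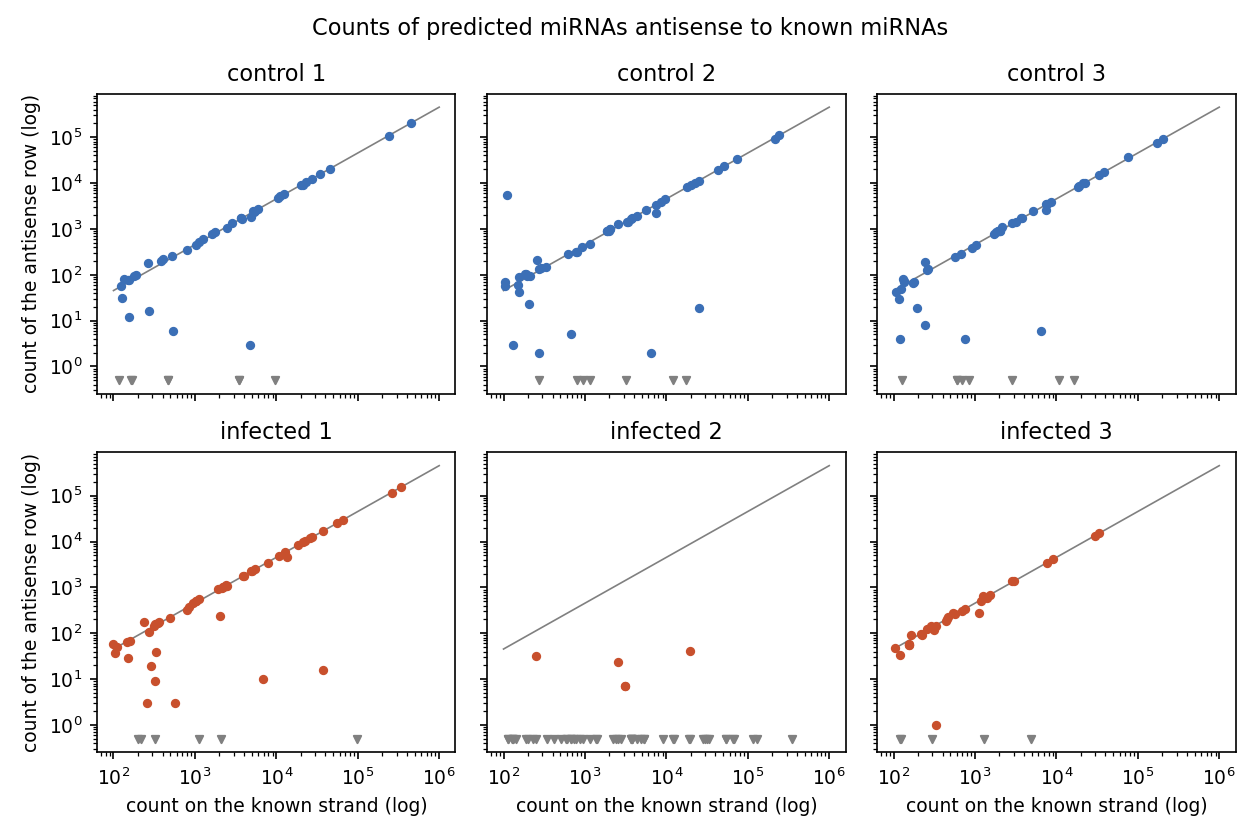
Each panel plots, for 1 library, the count of a predicted antisense row (vertical log axis) against the count of the known miRNA on the other strand (horizontal log axis), with grey triangles at the foot for antisense counts of 0 and a grey line at the median ratio of 0.453. Most points lie along the line in 5 libraries, while in infected library 2 the antisense count is 0 for 53 of 58 pairs.

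The main comparison asked which miRNAs of the spleen differ in level between infected and control fish. Of 261 miRNAs tested, 3 rose and 3 fell in infected spleens, and all 6 were listed at 0 in every library of 1 group. The 3 that rose were dre-miR-140-3p, best known from cartilage, and both arms of miR-222a, a regulator of cell proliferation that is clustered with miR-221 in vertebrate genomes. dre-miR-140-3p was at 2390 ± 597 CPM, dre-miR-222a-3p at 2924 ± 1095 CPM and dre-miR-222a-5p at 1145 ± 127 CPM in infected spleens (SD, n = 3 each). The 3 that fell were predicted miRNAs antisense to miR-143, miR-203a and miR-722, which stood at 20111 ± 7649, 29.9 ± 6.13 and 24.4 ± 5.34 CPM in control spleens (SD, n = 3 each).

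All 6 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with adjusted p = 0.00970 for dre-miR-140-3p, dre-miR-222a-5p and the antisense row of miR-143. The adjusted p was 0.0117 for dre-miR-222a-3p and 0.0458 for the antisense rows of miR-203a and miR-722. All 6 differed by more than 2-fold in the fitted model, but no fold is given, because a 0 in this table need not be a measured absence. The authors' sequence table listed no precursor for dre-miR-140-3p and the arms of miR-222a in any control library, and in all 133 cells of known miRNAs without a precursor the count was 0. Of all 211 cells of known miRNAs at 0, the other 78 had a listed precursor. A missing entry and a true absence would both leave a 0 without a precursor, so these cells do not separate them. For the 3 antisense rows, infected library 2 lacked nearly all antisense counts. The listed miR-222a precursor in the infected libraries was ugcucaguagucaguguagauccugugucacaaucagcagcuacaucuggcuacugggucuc. The antisense row of miR-140 had 741, 1048 and 813 counts in the controls, so reads of the locus may have been present there on the other strand. This row had 3 precursor entries over the libraries, and its match to miR-140 is that of the entry with the most counts. dre-miR-221-3p, from the cluster of miR-222a, had a log2 fold change of 0.79 and was counted in all 6 libraries (edgeR adjusted p = 0.526; DESeq2 5.43e-05, or 0.195 on the rows with a precursor in every library). The known-strand partners of the 3 rows that fell had log2 fold changes of 0.00 ± 0.43 (dre-miR-143-3p), -0.05 ± 0.75 (dre-miR-203a-3p) and -1.06 ± 1.25 (dre-miR-722-3p; SE), and none of them passed the test.

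**Figure D2:**
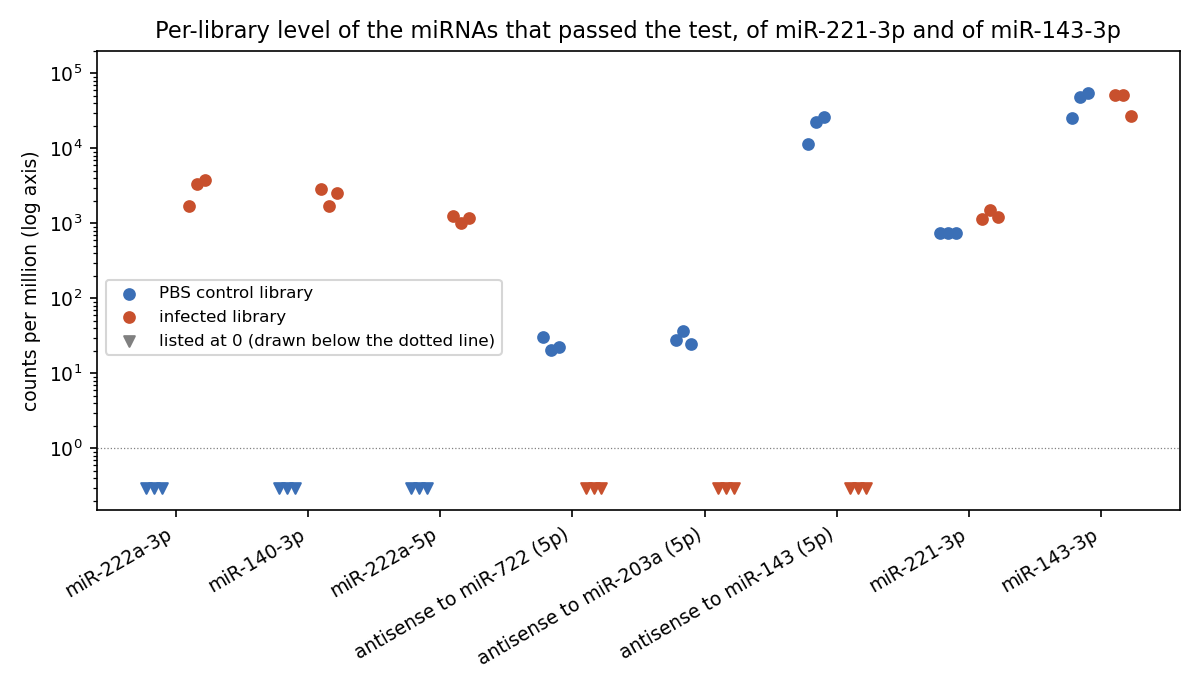
The level of each miRNA that passed the test, and of dre-miR-221-3p and dre-miR-143-3p, is plotted per library in CPM on a log axis, with control libraries in blue, infected libraries in orange and triangles for libraries listed at 0. The 3 miRNAs on the left are at 0 in all 3 controls and the next 3 are at 0 in all 3 infected libraries, while dre-miR-221-3p and dre-miR-143-3p are counted in all 6.

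Below the threshold, the smallest p-values among miRNAs with higher values in infected spleens belonged to dre-miR-2188-5p, dre-miR-204-5p, dre-miR-199-5p, dre-miR-125b-5p and dre-miR-92a-3p, with log2 fold changes of 1.36, 1.38, 0.89, 1.24 and 0.91. Those with lower values were dre-miR-146b-5p (log2 fold change -1.34 ± 0.27 SE), dre-let-7j-5p (-1.15), dre-let-7h-5p (-1.07), the antisense 3p row of miR-140 (-4.61) and dre-miR-190a-5p (-2.65). The antisense 3p row of miR-140 had 3, 0 and 0 counts in infected libraries 1, 2 and 3. Infected library 2 lacked nearly all antisense counts, and infected library 3 was the shallowest. dre-miR-146b-5p, a paralog of miR-146a, came closest, at 28078 ± 5510 CPM in controls and 11094 ± 1565 in infected spleens (SD, n = 3 each; edgeR adjusted p = 0.122). Each of these 10 had all 3 infected libraries on 1 side of all 3 controls, which their choice by small p-values favours. Of the 261 miRNAs tested, 61 did so (23.4%, where chance gives 10% for a single miRNA). The miRNAs are not independent and other splits of the libraries were not counted in this way, so the difference from 10% was not tested. DESeq2 called 7 of the 10: dre-miR-204-5p (adjusted p = 3.34e-05), dre-miR-199-5p (0.0107), dre-miR-146b-5p (0.000285), dre-let-7j-5p (2.46e-05), dre-let-7h-5p (2.42e-26), the antisense 3p row of miR-140 (0.000213) and dre-miR-190a-5p (0.0232). On the known miRNAs with a precursor in every library, DESeq2 kept dre-miR-146b-5p (0.0402) and dre-miR-190a-5p (0.00114) and lost dre-miR-204-5p (0.105), dre-miR-199-5p (0.161), dre-let-7j-5p (0.0671) and dre-let-7h-5p (0.0723) at similar folds, and the antisense row is not among these rows. Among the abundant miRNAs, dre-miR-462-5p had a log2 fold change of 0.41 ± 0.28, dre-miR-30c-5p of 0.64 ± 0.35, dre-miR-30d-3p of 0.28 ± 0.26 and dre-let-7e-5p of -0.70 ± 0.38 (SE), none past the test. The antisense rows of miR-146a and miR-21 had log2 fold changes of -0.81 ± 2.58 and -0.53 ± 2.53 (SE), with infected library 2 at 0 in both.

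**Figure D3:**
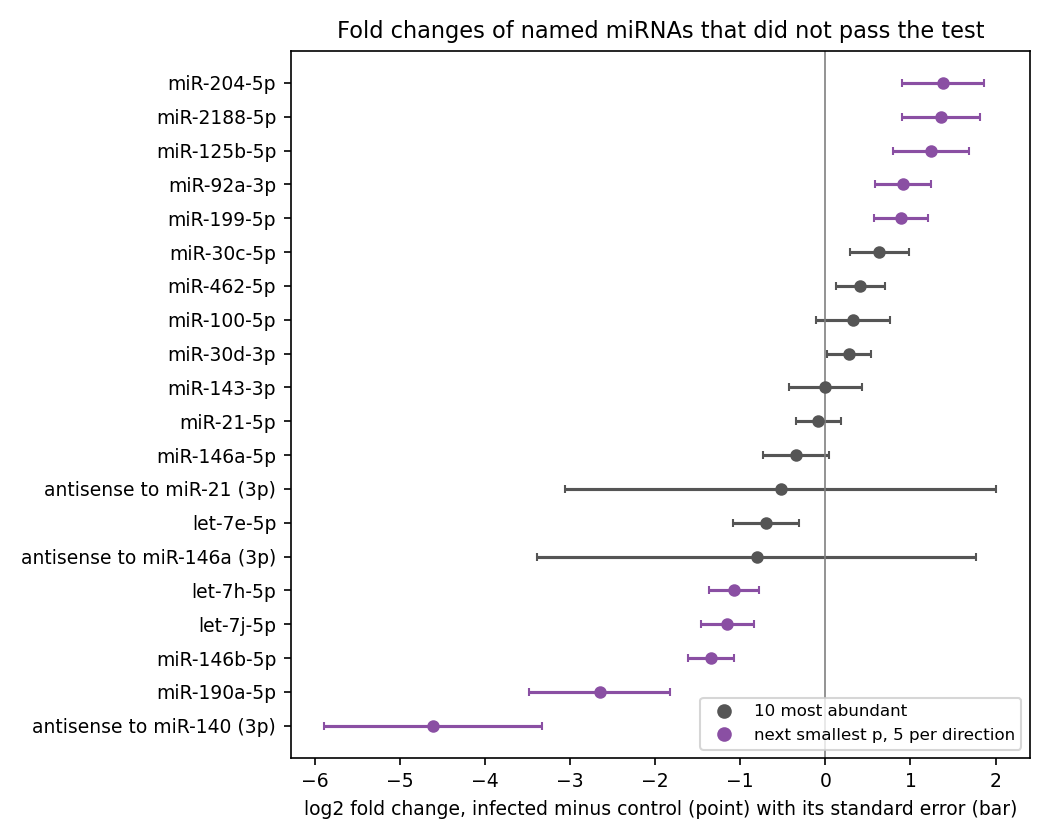
The log2 fold change of infected over control spleens (points) with its standard error (bars) is shown for 20 named miRNAs that did not pass the test, in grey the 10 most abundant and in purple the next smallest p-values. dre-miR-2188-5p lies at 1.36 and dre-miR-146b-5p at -1.34, while dre-miR-143-3p lies at 0.00.

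The test had little reach at the spread of all 261 miRNAs, with a common biological coefficient of variation of 1.11. These include 74 predicted rows. Among the 160 tested zebrafish-named miRNAs with a precursor in every library the coefficient was 0.497, and no simulation was run on those rows alone. In 10 simulated sets of the 261 miRNAs with 40 of them changed, the test recovered 0% of 8-fold and 63.2% of 64-fold changes. At 0.1 times the dispersion it recovered 90.5% of 8-fold changes. Counts of calls moved with each library left out: 4 higher and 2 lower without control library 1, 3 and 0 without control library 2, 3 and 0 without control library 3, 1 and 7 without infected library 1, 2 and 1 without infected library 2, and 0 and 0 without infected library 3. DESeq2 called 12 higher and 12 lower, 15 of them above 0 in both groups.

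The family lists asked whether miRNAs with a shared role moved together. Of 15 lists with at least 3 tested members, 1 moved: the inflammation-responsive list was higher in infected spleens (camera with a preset correlation of 0.01, adjusted p = 0.000857). The call was lost with an estimated correlation (adjusted p = 0.286 with an estimated correlation) and among miRNAs with a precursor in every library (adjusted p = 0.737), where both arms of miR-222a are left out. Of its 13 tested members, 2 rose and none fell, and both that rose were arms of miR-222a; adjusted over the list alone, 2 rose and 1 fell (dre-miR-146b-5p). dre-miR-155-5p, induced in activated macrophages and lymphocytes, was at 1272 ± 793 CPM in controls and 3482 ± 1179 CPM in infected spleens (SD, n = 3 each), with a log2 fold change of 1.45 ± 0.56 (SE) and an edgeR adjusted p = 0.540. The most abundant members, dre-miR-146a-5p and dre-miR-21-5p, had log2 fold changes of -0.34 ± 0.39 and -0.08 ± 0.27 (SE), and both turned positive without control library 1 (0.15 and 0.09). The median log2 fold change of the list was 0.50, while its summed level was 391240 ± 135788 CPM in controls and 328563 ± 49795 in infected spleens (SD, n = 3 each).

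The other immune and blood lists had no member that passed the main test. In the haematopoietic and myeloid list, 11 of 14 tested members had negative log2 fold changes (camera adjusted p = 0.448), with dre-miR-27b-3p at -0.48 ± 0.40 and dre-miR-23b-3p at 0.30 ± 0.32 (SE). One of the 11 was a predicted row, conserve-dre-miR-142-5p (-2.76 ± 2.00, SE), which is antisense to miR-142b and at 0 in infected library 2; without it 10 of 13 were negative. In the lymphocyte list, 5 of 7 were positive (adjusted p = 0.448), with dre-miR-181a-5p at 0.44 ± 0.65 (SE), which turned to -0.51 without infected library 2. In the miR-17-92 list, a family tied to lymphocyte growth, 11 of 16 were positive (adjusted p = 0.448), with dre-miR-92a-3p at 0.91 ± 0.33 and dre-miR-25-3p at 0.46 ± 0.39 (SE). The fish interferon-inducible cluster had 1 tested row, dre-miR-462-5p, at 31480 ± 2959 CPM in controls and 41880 ± 10704 in infected spleens (SD, n = 3 each). Erythroid dre-miR-144-5p was listed without a precursor, and at 0, in 2 of the 3 controls, and passed only without the third, control library 1 (adjusted p = 0.0323). The erythroid list as a whole had 2 tested rows and no list test.

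Among families expressed in many tissues, the let-7 list had 7 members positive and 7 negative of 14 tested (camera adjusted p = 0.914). fry's mixed test, which asks whether members change in either direction, gave an adjusted p = 0.0118 for this list, with dre-let-7a-5p at 0.55 ± 0.37 and dre-let-7e-5p at -0.70 ± 0.38 (SE). Summed over the family, the let-7 counts had a log2 fold change of -0.21 ± 0.34 (SE, edgeR adjusted p = 0.747). Reads could have moved between paralogs in the counting, so the mixed result need not mean that single members changed. In the miR-10/100/125 list, 8 of 12 were positive (adjusted p = 0.311), with dre-miR-100-5p at 0.33 ± 0.44, which turned to -0.0053 without infected library 2, and dre-miR-99-5p at 0.38 ± 0.44 (SE). In the miR-30 list, 4 of 7 were positive (adjusted p = 0.696). In the miR-15/16 list, 6 of 8 were positive (adjusted p = 0.493), with dre-miR-16b-5p at 0.66 ± 0.43 and dre-miR-16c-5p at 0.13 ± 0.37 (SE), the latter -0.12 without control library 1. All 4 tested rows of miR-29, of which dre-miR-29b-3p and dre-miR-29b3-3p had identical counts, were negative (adjusted p = 0.311), with dre-miR-29a-5p at -1.56 ± 1.60 and dre-miR-29a-3p at -1.27 ± 1.00 (SE). The hypoxia list (dre-miR-210-5p at 0.46 ± 0.41, SE) and the miR-34 list (dre-miR-34c-3p at 2.79 ± 2.39, SE, or 2.21 to 9.36 with 1 library left out) had 2 tested rows each and no list test.

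Markers of other tissues were measured for admixture, and no list of them passed. The striated muscle list summed to 520 ± 153 CPM in controls and 251 ± 52.0 in infected spleens (SD, n = 3 each; camera adjusted p = 0.914), led by dre-miR-1-3p at a log2 fold change of -1.40 ± 0.55 (SE, edgeR adjusted p = 0.559) and with dre-miR-206-3p at 1.07 ± 2.40 (SE), or -0.26 without infected library 1. The pancreas list summed to 1425 ± 302 and 817 ± 165 CPM (adjusted p = 0.914), with dre-miR-7b-5p at -0.90 ± 0.38 and dre-miR-7a-5p at -0.43 ± 0.63 (SE). The miR-200 epithelial list summed to 999 ± 111 and 536 ± 130 CPM, with all 5 tested members negative (adjusted p = 0.448), among them dre-miR-200b-3p at -0.82 ± 0.38 and dre-miR-200c-5p at -0.60 ± 2.38 (SE). DESeq2 called dre-miR-200b-3p lower (adjusted p = 0.0154, or 0.282 on the rows with a precursor in every library). The gut and kidney epithelium list summed to 1179 ± 631 and 881 ± 631 CPM (adjusted p = 0.914), with dre-miR-205-5p at -0.23 ± 2.68 (SE), which lay between -1.65 and 1.17 with 1 library left out. The neural list summed to 4618 ± 945 and 8598 ± 3472 CPM (adjusted p = 0.914), nearly all of it dre-miR-128-3p at a log2 fold change of 0.90 ± 0.38 (SE), while dre-miR-9-5p was at 20.0 ± 3.22 CPM in controls and 8.96 ± 8.50 in infected spleens (SD, n = 3 each), with a log2 fold change of -1.004 ± 0.921 (SE). The endothelial and smooth muscle list summed to 58803 ± 20499 and 57519 ± 17972 CPM (adjusted p = 0.914), with dre-miR-143-3p at 0.00 ± 0.43 and dre-miR-126b-3p at 0.55 ± 1.62 (SE), the latter -0.04 without control library 2. In control library 2, dre-miR-126b-3p had 54 counts and its paralog dre-miR-126a-3p 22220, while dre-miR-126a-3p had 0 to 2 counts in the other 5 libraries. Liver dre-miR-122-5p was at 109 ± 13.4 CPM in controls and 121 ± 162 in infected spleens (SD, n = 3 each), and its log2 fold change of 0.16 turned to -2.03 without infected library 2. For let-7, striated muscle, and endothelial and smooth muscle, camera gave the direction up although the median log2 fold changes were -0.15, -0.36 and -0.11, against a median of -0.12 over all miRNAs tested.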

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

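The tests that used subsets of rows by precursor, sums per family, rows with identical counts collapsed, known miRNAs without an infected library, known miRNAs only for the lists, and quality weights or DESeq2 on such rows were chosen after the data were seen; the others were chosen before the data were examined. Against 3 higher and 3 lower miRNAs, DESeq2 gave 12 and 12 (83 adjusted p-values were NA), and the lower count was 1 with limma voom with quality weights, with upper quartile scaling, with library size only and without a low-count filter, 0 with known miRNAs only, and 0 with known miRNAs only and either infected library 2 or infected library 3 left out. The 3 lower miRNAs of the main test were predicted rows, so settings with known miRNAs only left them out by construction. Sums per family, which also used known miRNAs only, gave 1 higher (miR-140) and 0 lower. Known miRNAs with a precursor in every library gave 0 and 0 by edgeR (28 at an unadjusted p under 0.05), 1 higher and 2 lower by DESeq2, and 5 higher and 6 lower by limma voom with quality weights. The 1 higher by DESeq2 was dre-miR-218a-3p (adjusted p = 7.58e-07), listed at 0 in every library of 1 group although its precursor was listed. All 6 original calls lie outside these rows by construction. With 1 library left out the higher count ranged from 0 to 4 and the lower from 0 to 7; the cause was not tested beyond the smaller number of libraries. With the replicate number as a block, 0 were higher and 0 lower, and same-numbered libraries did not deviate together (r = 0.018, -0.039 and -0.079). The number of passing lists was 0 with an estimated correlation and 0 among known miRNAs with a precursor in every library, and 1 in all other settings run. The inflammation-responsive list kept its call in 16 of 18 settings, with adjusted p between 0.000303 and 0.737 over all 18 and between 0.000303 and 0.0164 when 1 library was left out. Both arms of miR-222a were left out only among known miRNAs with a precursor in every library. The other settings therefore cannot show whether the call rests on these arms. The top 10 share difference ranged from -3.59 to 2.03 points with 1 library left out. Collapsing the 1 pair of tested rows with identical counts kept 3 higher, 3 lower and 1 list. RLE scaling, the stricter filter, the removal of the 3 most abundant miRNAs and the threshold of 0.1 kept both counts within 1.5 times. The median log2 fold change was -0.12 with TMM scaling, 0.08 with upper quartile scaling and 0.02 with library size only, and -0.36 in limma voom with quality weights, so signs of small values are relative to it.

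Directions changed only for miRNAs and lists that had not passed, and the cause was not tested. Log2 fold changes with quality weights were 0.090 for dre-miR-146a-5p, 0.083 for dre-miR-21-5p, -0.22 for dre-miR-143-3p, -1.15 for dre-miR-122-5p, 2.67 for dre-miR-205-5p and -0.077 for dre-miR-16c-5p. dre-miR-21-5p was at 0.077 and dre-miR-205-5p at 0.17 with the upper quartile, and at 0.080 and 0.19 with library size only. dre-miR-143-3p was at -0.014 without a filter, -0.031 with known miRNAs only and -0.044 with a precursor in every library. The stricter filter gave -0.21 for dre-miR-143-3p, -0.30 for dre-miR-122-5p and -0.032 for dre-miR-16c-5p, and the block gave -0.92 for dre-miR-122-5p. Known miRNAs without infected library 2 gave 0.13 for dre-miR-21-5p, -0.11 for dre-miR-143-3p, -0.32 for dre-miR-181a-5p and -1.87 for dre-miR-122-5p, and without infected library 3 gave 0.30 for dre-miR-205-5p and -0.0047 for dre-miR-16c-5p. With 1 library left out, the ranges were -0.0053 to 0.63 for dre-miR-100-5p, -2.03 to 0.64 for dre-miR-122-5p, -0.039 to 1.52 for dre-miR-126b-3p, -0.26 to 0.24 for dre-miR-143-3p, -0.55 to 0.15 for dre-miR-146a-5p, -0.12 to 0.31 for dre-miR-16c-5p, -0.51 to 0.91 for dre-miR-181a-5p, -1.65 to 1.17 for dre-miR-205-5p, -0.26 to 8.72 for dre-miR-206-3p and -0.25 to 0.091 for dre-miR-21-5p. Ranges that kept their sign but spanned at least 3-fold were 0.29 to 12.89 for dre-miR-144-5p, 2.21 to 9.36 for dre-miR-34c-3p, -3.98 to -1.01 for dre-miR-29a-5p, -1.21 to -0.017 for dre-miR-200c-5p, -1.17 to -0.093 for dre-miR-7a-5p, 0.0064 to 0.72 for dre-miR-99-5p, 0.15 to 0.73 for dre-miR-25-3p, 0.097 to 0.64 for dre-miR-210-5p, 0.025 to 0.43 for dre-miR-23b-3p, -0.70 to -0.22 for dre-miR-27b-3p, and -1.25 to -0.31 and -1.08 to -0.038 for the antisense rows of miR-146a and miR-21. dre-miR-144-5p gained a call without control library 1 (adjusted p = 0.0323), the only control in which it was counted, and dre-miR-200b-3p with DESeq2 (adjusted p = 0.0154).

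Lists whose direction changed had these adjusted p-values. fry gave 0.812 (let-7), 0.953 (endothelial and smooth muscle) and 0.599 (striated muscle). No filter gave 0.963 (let-7 and neural) and 0.852 (gut and kidney epithelium), and the stricter filter 0.987 (let-7). Known miRNAs only gave 0.966 (let-7 and striated muscle) and 0.979 (endothelial and smooth muscle). A precursor in every library gave 0.737 (let-7), 0.954 (endothelial and smooth muscle, and miR-30) and 0.823 (striated muscle). Known miRNAs without infected library 2 gave 0.827 (let-7, and endothelial and smooth muscle) and 0.846 (striated muscle), and without infected library 3 gave 0.671 (miR-17-92, let-7 and striated muscle) and 0.921 (endothelial and smooth muscle, gut and kidney epithelium, and miR-30). With 1 library left out the ranges were 0.718 to 0.963 (endothelial and smooth muscle), 0.666 to 0.963 (gut and kidney epithelium), 0.727 to 0.908 (let-7), 0.537 to 0.997 (neural), 0.893 to 0.946 (pancreas) and 0.838 to 0.995 (striated muscle). Collapsing rows with the same mature sequence was not run, because mature sequences were not used here, and the pseudocount applied only to normalized values.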

Other observations

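Among 160 tested zebrafish-named miRNAs whose precursor was listed in every library, the common biological coefficient of variation was 0.497, against 1.11 over all 261. The tests on these rows and on the antisense rows, except the count of library splits, were chosen after the data were seen. limma voom with quality weights called 11 of them. Higher in infected spleens were dre-miR-155-5p (log2 fold change 1.76, limma adjusted p = 0.0227), dre-miR-2188-5p (1.60, 0.0227), dre-let-7c-3p (1.83, 0.0227), dre-miR-204-5p (1.31, 0.0454) and dre-miR-15b-5p (1.39, 0.0470). Lower were dre-miR-146b-5p (-1.28, 0.0227), dre-let-7j-5p (-1.28, 0.0227), dre-let-7h-5p (-1.08, 0.0227), dre-let-7f-3p (-1.13, 0.0454), muscle dre-miR-1-3p (-1.81, 0.0227) and dre-miR-190a-5p (-2.97, 0.0227). The weights were 0.489, 2.45 and 2.41 for control libraries 1, 2 and 3 and 1.05, 0.667 and 0.494 for infected libraries 1, 2 and 3, so control libraries 2 and 3 carried most of the control mean and infected library 1 the largest part of the infected mean. The groups overlapped in dre-miR-15b-5p and dre-let-7f-3p. On the same rows edgeR's smallest adjusted p was 0.1497, and DESeq2 called dre-miR-146b-5p (adjusted p = 0.0402) and dre-miR-190a-5p (0.00114) among these 11. The 6 calls of the main test were the most that any split of the 6 libraries gave: 1 of 10 splits reached 6 and the highest of the other splits gave 1, but 10 splits cannot give a share under 0.05.

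Known miRNAs listed at 0 in every control and counted in every infected library are the first pattern. dre-miR-140-3p may have been sequenced in the controls too and left out because no precursor was annotated there, since its antisense row had at least 741 counts in each control. That row had 3 precursor entries over the libraries, and its match to miR-140 was taken from the entry with the most counts. A higher level in infected spleens remains open. Scaled to the zebrafish-named counts, as CPM, the antisense row stood at 758 ± 151 in controls (SD, n = 3). It stood at 1618 and 1589 in infected libraries 1 and 3, 2.12 times the control mean (exact two-sided permutation p = 0.1, the smallest possible). Infected library 2 was left out of this comparison, with an antisense count of 0 and 4332 counts on the known strand. The antisense 3p row of miR-140 went the other way, with 20, 22 and 37 counts in controls and 3, 0 and 0 in infected libraries (log2 fold change -4.61, edgeR adjusted p = 0.351; -3.92 without infected library 2 and -7.71 to -3.92 with 1 library left out). For miR-222a no antisense row exists, its paralog dre-miR-222b-3p had 344 counts in control library 2 and 0 elsewhere (family sums of 98.5 ± 171 CPM in controls and 4999 ± 1429 in infected spleens, SD, n = 3 each; edgeR adjusted p = 0.376), and dre-miR-221-3p of the same cluster, counted in every control, had a log2 fold change of 0.79 (edgeR adjusted p = 0.526, DESeq2 5.43e-05), so an unlisted precursor and a true absence in the controls cannot be told apart.

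Predicted miRNAs that mirror known precursors are the second pattern. A candidate explanation is that reads of both strands of the same loci were counted, but 67.5% of pairs lay within 1.2-fold of 1 ratio per library, short of the 70% set for it (77.8% without the 34 pairs at 0). Separately transcribed antisense strands would give each locus its own ratio. Over all pairs the upper quartile was 1.58 times the lower, between the 1.5 and 4 set. Without the 34 pairs at 0 it was 1.10 times the lower, below both limits. Within single libraries, infected library 2 left out, it was 1.08 to 1.13 times, around median ratios of 0.441 to 0.458. For most pairs with a nonzero antisense count, these values argue against separate transcription. For the pairs at 0 and those outside 1.2-fold, the 2 explanations cannot be told apart. Antisense counts of 1 locus could also stand in different rows by library. The antisense 5p row of miR-22a had 5685, 0 and 0 counts in control libraries 1, 2 and 3, and its antisense 3p row had 0, 5416 and 4894. A 0 in 1 row therefore need not mean that the locus had no antisense counts. Infected library 2, at 0.0290% antisense counts, may have been handled differently from the other 5 libraries in this respect; 53 of its 58 pairs had an antisense count of 0. No biological explanation was tested for it, and which step differed is not recorded in the sources used here.

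Antisense rows counted in every control and at 0 in every infected library are the third pattern. A fall of the known miRNAs at these loci was tested first: the lowest log2 fold change of the 3 partners was -1.06 ± 1.25 (SE, dre-miR-722-3p), above the value of -3 that was set as the least fall needed. At the median ratio of infected library 1, the antisense row of miR-203a would have had 97.2 counts and that of miR-143 43829, where 0 were listed, so antisense counts may have been left out of the table at these loci. For miR-722 the count at that ratio was 9.49, too few to decide, and a lower level there cannot be told apart from a missing entry.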
